A study of Mus musculus with 6 samples.

How the data were processed

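Liver RNA of fasted mice lacking CREBH (CREBH-KO), a liver transcription factor encoded by Creb3l3, was compared with that of wild-type (WT) mice by RNA sequencing, with 3 samples per genotype. Per the labels, total RNA was taken after a fast of 14 h, had an RNA integrity number above 8, and was sequenced as paired-end reads in 1 lane of a HiSeq 4000. The labels of CREBH-KO 2 and CREBH-KO 3 say that a file of first reads was lost; how the counts of these libraries were made from the remaining files is not stated. Replicate numbers only name the libraries and pair none of them. The labels call the samples of a group independent without saying that each came from its own mouse. The p-values therefore measure the spread between these samples.

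The authors deposited 1 file of read counts per library, and HTSeq is named in the sample titles, per the labels. The aligner, the genome build, the HTSeq version and its strand setting are not given in the sources used here. All 55536 gene identifiers of each file matched the identifiers of GENCODE M21 (GRCm38), which supplied gene symbols and positions; the build was inferred from this match. HTSeq's summary lines for reads given to no gene held 27.4% to 31.2% of the listed reads per library (no annotated gene, 7.96% to 10.4%; ambiguous, 5.81% to 6.45%; aligned to several places, 13.7% to 15.0%) and were left out of library sizes and tests. Since reads aligned to several places were set aside, genes with near-identical copies (Mup, Cyp2a, Cyp2b, Cyp2c, Cyp4a, Serpina1, Acot, Gstm, Hspa1a and Hspa1b, Hamp and Hamp2) are uncertain. So are genes that overlap others. With the strand setting unknown, reads from antisense partners cannot be told apart. Of the exonic bases of Apoa4, 69.8% lie within antisense genes, and of those of Rhbg 61.4% within a gene of the same strand. The share was 20.8% for Apoa5, 23.1% for Mpc1, 20.6% for Acot3 and 22.8% for Ube2c with overlapping genes on either strand.

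Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 15589 genes with 99.9% of the counts. Libraries were scaled with TMM factors (0.967 to 1.05), and edgeR's quasi-likelihood test compared CREBH-KO with WT, with no covariate. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are CREBH-KO minus WT, given with standard errors (SE). The SE of a gene was derived as its absolute log2 fold change divided by the square root of the test's F statistic. Normalised counts, scaled to CPM by effective library size, are given as mean ± SD. Tests are two-sided. For genes with 3 or fewer counts over a group, a ratio of counts with its 95% exact interval is given, or, at 0 counts, a bound against a floor of 3 counts over the group; both cover counting error only. Replicates of a group differed beyond sampling noise in every pair (chi-square per degree of freedom of at least 18.3), so no library was counted as a copy of another.

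In counts simulated from the real means, library sizes and dispersions for 15589 genes, 15235 of which passed the filter, the test recovered 29.9% of 67 genes changed 1.5-fold, 80.6% of 67 changed 2-fold and 92.4% of 66 changed 4-fold, and 7.14% of its calls were unchanged genes. These 200 genes were drawn from genes with a mean above 1 CPM that were in no list. Far fewer genes were changed than the 1616 called in the real data, so recovery there may differ. Of 36 unshifted gene lists, 1 was called. Genes were simulated independently of each other, so this count does not cover false calls of lists whose genes vary together. In the real data the estimated correlation was 0.88 for the list of mitochondrial genome-encoded mRNAs.

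Before the data were examined, 41 gene lists were fixed: 12 core lists of stress responses and fasting metabolism, and further lists of liver functions and of markers of other cell types. The 38 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, were run beside it. Members are counted at p adjusted over all genes tested and at p adjusted over the list alone. None of the 17 lists called by camera with the preset correlation kept its call with an estimated correlation. By fry, 10 of these 17 did not pass (adjusted p of 0.0540 to 0.305). They were the lists of reported CREBH targets, PPAR-alpha targets, cholesterol synthesis, gluconeogenesis, bile acid genes and male-biased genes. The lists of immediate early, cytosolic heat shock and cytosolic ribosomal protein genes and of stellate cell markers did not pass either.

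Named genes followed a rule fixed at the same time: Creb3l3; the 10 largest rises and 10 largest falls among changed genes with at least 1 CPM in the higher group, no overlap between the groups and a named symbol; up to 4 changed members of each core list and 2 of each other list, by p-value; and 13 fixed names. Some genes that this rule names are not reported here. Cidec, Pdk4, G6pc, Arntl, Npas2, Per2, Per3, Scd1, Thrsp, Glul, Cyp2e1, Rhbg, Cyp4a14, Acot1, Acot2, Plin2, Trap1, Foxo3, Asns, Mthfd2, Trib3, Elovl2, Hsd3b5, Cyp7b1, Mup7, Acta2, Lyrm7, Gadd45b, Tmem86a and Hamp2, and genes named beside a count of 5 or fewer, were chosen after their values were seen.

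Alternatives were RLE, upper-quartile and library-size scaling, no filter and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, edgeR's robust fit, other thresholds, leaving out each library, leaving out both libraries with a lost read file, and leaving out genes of the mitochondrial genome. Corrections for GC content and gene length, and fits without gene families picked by symbol or without part of chromosome 11, were added after the data were seen. The families were all Mup, Cyp, Serpina, Gstm and Olfr genes and several Acot genes. They include genes outside the near-identical groups named above, such as Cyp27a1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.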

Results

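Gene expression was measured in the livers of CREBH-KO and WT mice after a 14 h fast, with 3 libraries per genotype. CREBH is a membrane-bound transcription factor of hepatocytes that is released by proteolysis and is known from work on fasting, lipid metabolism and stress responses. Reads counted in genes numbered 39288819, 33063836 and 31679996 in WT 1, 2 and 3. They numbered 34146918, 28106243 and 31951365 in CREBH-KO 1, 2 and 3. The first principal component held 48.0% of the variance and separated the genotypes. Xist stayed between 0.0626 and 0.527 CPM and the Y-linked Ddx3y between 65.5 and 103 CPM in all 6 libraries. The ribosomal RNA locus CT010467.1 took 0.567% to 1.44% of the counts, and both ends of that range were CREBH-KO libraries (CREBH-KO 2 and CREBH-KO 1).

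The design asks how liver expression during fasting differs without CREBH. Creb3l3 (ENSMUSG00000035041), on the minus strand of chromosome 10 from 81084324 to 81098874 (GRCm38), fell from 486 ± 16.6 CPM in WT to 49.6 ± 6.79 CPM in CREBH-KO (SD, n = 3 each). Its log2 fold change was -3.29 ± 0.11 (SE, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.00e-06), or 9.79-fold. Creb3l3 was lower in each CREBH-KO library than in any WT library. The labels do not say which exons the knockout lacks, so the remaining counts can include transcript from outside the deleted part.

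The genes with the steepest rises in CREBH-KO included Sema3g, a secreted semaphorin, at 28.7-fold, and Bmper, a binding protein of bone morphogenetic proteins, at 14.3-fold. Fst (follistatin), an activin antagonist, rose from 1.51 ± 0.676 to 20.6 ± 6.91 CPM. Havcr1, known as an injury marker of the kidney, had 2 counts over the WT libraries and 264 over the CREBH-KO libraries, a ratio of 139 (95% exact interval 38.05 to 1152). Frmd5 had 0 counts in WT and 108 in CREBH-KO and was at least 37.9-fold higher against a floor of 3 counts over the group. Tcf24, Cyp2b9, Klhl33, Tox2 and Sybu, with log2 fold changes of 3.69 to 5.38, completed the 10 largest rises. The adipsin gene Cfd had 174 counts over WT against 1, a ratio of 165 with a 95% exact interval of 29.3 to 6573. The other steepest falls were those of Btnl9, Dntt, the vaspin gene Serpina12, Pttg1 (securin), the clock output gene Dbp, Tnfaip8l1, Gpc1, the clock gene Ciart and the organic anion transporter Slc22a7. Serpina12 fell from 12.5 ± 4.26 to 0.552 ± 0.104 CPM, and Pttg1 from 29.5 ± 2.63 to 1.68 ± 0.481 CPM (SD, n = 3). The call of Ciart was lost in limma-voom (adjusted p = 0.0826) and in edgeR's robust fit (adjusted p = 0.0690).

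In total, 1616 of 15589 tested genes changed, 609 upwards and 1007 downwards, and 555 changed at least 2-fold, 280 upwards and 275 downwards (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment). The groups did not overlap for 1614 of the changed genes and for 30.6% of all tested genes, where chance gives 10%. Higher genes made up 37.7% of the calls with TMM scaling and 52.8% with scaling by library size alone, and all 1616 genes kept their direction in both. The number of changed genes fell to 658 without WT 2, to 838 without CREBH-KO 2, to 778 without CREBH-KO 3 and to 228 when only CREBH-KO 1 was set against WT.

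The series title names the mitochondrial unfolded protein response, a program in which nuclear genes for mitochondrial chaperones and proteases are switched on when protein misfolds in the organelle. Of its 26 listed genes, 1 rose, 6 fell and 19 did not pass the test. Adjusted over the list alone, 1 rose and 8 fell. The largest change was in Atf5, a transcription factor of this response, which fell from 624 ± 68.2 to 299.9 ± 12.1 CPM (log2 fold change -1.06 ± 0.10 SE, n = 3, edgeR adjusted p = 4.36e-04). The other falls were smaller: the chaperone genes Dnaja3 (-0.32) and Trap1 (-0.29), the protease gene Spg7 (-0.32), the mitochondrial deacetylase Sirt3 (-0.33) and the transcription factor Foxo3 (-0.69), on the log2 scale. Hspe1, the co-chaperonin of HSP60, rose by 0.29. The HSP60 gene Hspd1 did not pass (log2 fold change -0.05 ± 0.09, edgeR adjusted p = 0.787). Nor did the protease genes Lonp1 (-0.28 ± 0.08, adjusted p = 0.0653) and Clpp (0.16 ± 0.08, adjusted p = 0.263). Lonp1 passed in DESeq2 (adjusted p = 0.0274) and with no filter on low counts (adjusted p = 0.0403). As a set the list had a median log2 fold change of -0.05 and did not pass (camera adjusted p = 0.0750; adjusted p = 0.459 with an estimated correlation). With 1 library left out the median ranged from -0.090 to -0.019 and the list did not pass. The sign of the median depended on the scaling: it was 0.029 with library size alone (camera adjusted p = 0.222) and -0.010 with upper-quartile factors. The list passed with no filter on low counts (adjusted p = 0.00692) and by fry (adjusted p = 0.0317). The call of Hspe1 was lost without any 1 of the 6 libraries and those of Dnaja3, Spg7, Sirt3, Trap1 and Foxo3 without any 1 except WT 1 (adjusted p up to 0.156). Scaling by library size alone ended those of Dnaja3, Spg7, Sirt3 and Trap1 (adjusted p of 0.0731 to 0.114) and turned Hspd1 to 0.03.

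Genes of the unfolded protein response of the endoplasmic reticulum went both ways. Of 28 tested, Dnajb9, a chaperone cofactor, rose (log2 fold change 0.45 ± 0.08 SE, edgeR adjusted p = 0.00838) with Syvn1 (0.40). The coat protein gene Sec24d (-0.58 ± 0.08, edgeR adjusted p = 0.00274) fell with Derl1 (-0.28). Adjusted over the list alone, 3 rose and 2 fell. The list did not pass as a set (camera adjusted p = 0.602; adjusted p = 0.908 with an estimated correlation). The calls of Derl1 (without any 1 library) and Syvn1 (without any 1 except CREBH-KO 2) were lost, with adjusted p up to 0.166.

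The integrated stress response, in which ATF4 induces amino acid synthesis and stress genes, was higher as a list. Of its 23 tested members, 6 rose and 3 fell (8 and 3 adjusted over the list alone). The stress hormone Gdf15 rose from 5.66 ± 0.768 to 21.1 ± 8.00 CPM (log2 fold change 1.90 ± 0.27 SE, n = 3, edgeR adjusted p = 0.00324). The lipoprotein receptor Vldlr, the serine synthesis gene Psat1, the asparagine synthetase Asns, the folate enzyme Mthfd2 and Ddit3 (CHOP) rose by 0.71 to 2.34. Shmt2, the mitochondrial serine hydroxymethyltransferase, fell by 0.54 and the pseudokinase gene Trib3 by 1.15 on the log2 scale. Atf4 itself had a log2 fold change of 0.33 ± 0.13 and did not pass (edgeR adjusted p = 0.156), although it passed without WT 1 (0.49, adjusted p = 0.0114). The list had a median log2 fold change of 0.36 (camera adjusted p = 0.0250; adjusted p = 0.294 with an estimated correlation). Its call was lost without WT 1 (adjusted p = 0.107). Single calls were lost for Psat1 without WT 2 or CREBH-KO 3, Asns without WT 2, Trib3 without CREBH-KO 3, Mthfd2 without any 1 library except CREBH-KO 1 and Ddit3 without any 1 except WT 3, with adjusted p up to 0.123.

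Among 15 genes reported in earlier work as CREBH targets in lipoprotein, hormone and acute phase functions, 7 fell and 4 rose. The counts were the same adjusted over the list alone. Among the apolipoprotein genes, Apoa4, made in gut and liver, fell from 76.6 ± 28.5 to 18.4 ± 2.45 CPM (log2 fold change -2.05 ± 0.24 SE, edgeR adjusted p = 0.00144). Apoa1, the main protein of HDL, fell by 1.06 ± 0.14 and Apoa5, which regulates plasma triglycerides, by 0.77 ± 0.08 on the log2 scale. The fasting hormone gene Fgf21 fell from 3.74 ± 1.80 to 0.759 ± 0.280 CPM (-2.31 ± 0.40, edgeR adjusted p = 0.00810). The lipid droplet gene Cidec fell from 23.3 ± 11.4 to 3.74 ± 0.560 CPM (-2.63 ± 0.36). In the other direction, Hamp, which encodes the iron hormone hepcidin, rose from 595 ± 128 to 1232 ± 58.8 CPM (1.05 ± 0.14, edgeR adjusted p = 0.00274), and Hamp2 rose by 0.90 ± 0.16. The list was lower as a set, with a median of -0.56 (camera adjusted p = 0.0171; adjusted p = 0.367 with an estimated correlation). The median was -0.22 without WT 1, where the list still passed. The set's call was lost in limma-voom (adjusted p = 0.0901) and against CREBH-KO 1 alone (adjusted p = 0.403). The counts of Apoa4 can include its antisense genes.

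**Figure D1:**
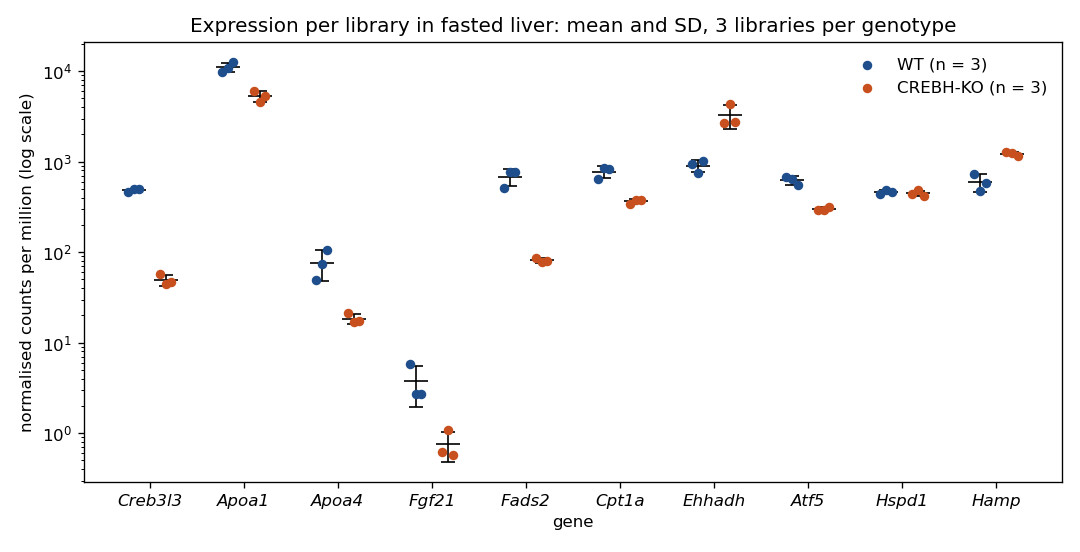
Normalised counts in CPM (log axis) of 10 genes in the 3 WT (blue) and 3 CREBH-KO (orange) libraries; points are libraries, horizontal marks the mean and error bars the SD. Creb3l3 lies at 486 CPM in WT and 49.6 CPM in CREBH-KO on average, and the groups do not overlap for any gene shown except Hspd1.

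Fatty acid synthesis genes were lower in CREBH-KO. Of 19 tested, 10 fell, none rose and 9 did not pass (11 fell adjusted over the list alone). Fads2, a desaturase gene of polyunsaturated fatty acid synthesis, fell from 683 ± 142 to 81.7 ± 4.79 CPM (log2 fold change -3.06 ± 0.15 SE, n = 3, edgeR adjusted p = 1.64e-05) and its relative Fads1 by 1.35 ± 0.13 on the log2 scale. The elongase genes Elovl5 (-1.37 ± 0.10) and Elovl2 (-1.64 ± 0.09, not on the list) and Srebf1 (-1.23 ± 0.15), which encodes the lipogenic transcription factor SREBP-1, also fell, as did the desaturase Scd1 (-1.26) and Thrsp (-1.90). As a set the list had a median of -0.39 (camera adjusted p = 4.89e-13; adjusted p = 0.294 with an estimated correlation). The calls of Scd1 (without WT 2, CREBH-KO 2 or CREBH-KO 3) and Thrsp (without these or WT 3) were lost, with adjusted p up to 0.0955, as they were in edgeR's robust fit (0.0731 and 0.107).

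Of 25 cholesterol synthesis and uptake genes, 6 fell and none rose (8 fell adjusted over the list alone). The sterol carrier gene Stard4 fell by 0.61 ± 0.12 and the sterol reductase gene Tm7sf2 by 0.58 ± 0.13 on the log2 scale (SE, n = 3, edgeR adjusted p = 0.0164 and 0.0262). The median of these genes was -0.15 (camera adjusted p = 0.00478; adjusted p = 0.698 with an estimated correlation). It was -0.09 without WT 1, -0.25 without WT 3 and -0.34 without CREBH-KO 2. The set's call was lost without WT 1 (adjusted p = 0.0698) or CREBH-KO 1 (0.0747), that of Stard4 without WT 2 or CREBH-KO 3 and that of Tm7sf2 without WT 2, CREBH-KO 2 or CREBH-KO 3 (adjusted p up to 0.107).

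Targets of PPAR-alpha, the nuclear receptor that drives fatty acid use in fasting, split into genes that rose and genes that fell. Ppara itself fell from 130.3 ± 25.1 to 53.7 ± 5.87 CPM (log2 fold change -1.28 ± 0.14 SE, n = 3, edgeR adjusted p = 0.00114). Of 33 tested targets, 13 rose and 7 fell (17 and 8 adjusted over the list alone). Risers included the peroxisomal enzyme Ehhadh, from 902 ± 129.9 to 3260.5 ± 959 CPM (1.85 ± 0.20), and the omega-hydroxylases Cyp4a14 (1.25 ± 0.14) and Cyp4a31 (0.94 ± 0.09). The thioesterases Acot1 (1.77 ± 0.20) and Acot2 (1.87 ± 0.28), the kinase gene Pdk4 (3.05 ± 0.51), which restrains pyruvate oxidation, and the lipid droplet gene Plin2 (1.03 ± 0.19) rose as well. Fallers, besides Fgf21, Cidec and Creb3l3 itself, included Plin4 (-1.30 ± 0.10) and Tmem86a (-1.32 ± 0.23). The list median was 0.31 (camera adjusted p = 0.0327; adjusted p = 0.711 with an estimated correlation). The call was lost without WT 1, WT 2 or WT 3 (adjusted p of 0.119, 0.0602 and 0.0679), with the stricter filter (0.0502) and against CREBH-KO 1 alone. It was also lost without the gene families picked by symbol, where the set's direction reversed (0.434). The call of Plin2 was lost without WT 2 (adjusted p = 0.0535) and that of Pdk4 in edgeR's robust fit (0.0678).

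Of 28 genes of fatty acid beta-oxidation, 2 rose and 4 fell (5 and 6 adjusted over the list alone). Besides Ehhadh, the peroxisomal carnitine acyltransferase gene Crot rose (0.67). Cpt1a, which encodes the rate-limiting enzyme of mitochondrial fatty acid entry, fell from 773 ± 114 to 368 ± 20.96 CPM (log2 fold change -1.07 ± 0.12 SE, n = 3, edgeR adjusted p = 8.80e-04). The reductase Decr2 fell by 0.81 ± 0.10 and the dehydrogenase Hadh by 0.40 on the log2 scale. Of 6 ketogenesis genes, 2 fell and 1 rose. Bdh1, the ketone body dehydrogenase, fell from 311 ± 35.0 to 159 ± 22.8 CPM (-0.97 ± 0.12, edgeR adjusted p = 0.00214). The monocarboxylate transporter gene Slc16a1 rose by 1.11 ± 0.20 on the log2 scale. Neither list passed as a set (camera adjusted p = 0.882 and 0.675; adjusted p = 0.961 and 0.836 with an estimated correlation). The median (0.08) and mean (0.06) of the ketogenesis list were above 0 while its test pointed down. The counts of ketogenesis genes were the same adjusted over the list alone. The calls of Hadh (without WT 2, CREBH-KO 1 or CREBH-KO 3) and Slc16a1 (without WT 2) were lost, with adjusted p up to 0.0880.

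Gluconeogenesis genes also went both ways: of 15, 4 fell and 1 rose, with the same counts adjusted over the list alone. The mitochondrial pyruvate carrier gene Mpc1 fell by 0.71 ± 0.09 and the alanine aminotransferase Gpt2 by 0.71 ± 0.10 on the log2 scale (SE, n = 3, edgeR adjusted p = 0.00244 and 0.00324), with pyruvate carboxylase Pcx (-0.75) and the PEP carboxykinase Pck1 (-0.64). The glucose-6-phosphatase gene G6pc rose by 0.74 ± 0.19, and the coactivator gene Ppargc1a did not pass (-0.34 ± 0.12, edgeR adjusted p = 0.125). The list median was -0.26 (camera adjusted p = 0.0412; adjusted p = 0.698 with an estimated correlation). The median was -0.43 without WT 1 and -0.13 without WT 3. The call was lost without WT 2, WT 3 or CREBH-KO 2 (adjusted p of 0.0755, 0.211 and 0.0838), against CREBH-KO 1 alone (0.0889) and under upper-quartile scaling (0.0533), the stricter filter (0.0775) and limma-voom (0.0571). The calls of Pcx (without WT 2, CREBH-KO 2 or CREBH-KO 3), Pck1 (without these or WT 3) and G6pc (without any 1 library except WT 1, and in edgeR's robust fit) were lost, with adjusted p up to 0.143.

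Tricarboxylic acid cycle genes were lower as a list: of 21, 8 fell and 1 rose (9 and 1 adjusted over the list alone). The succinyl-CoA ligase genes Suclg1 and Suclg2 fell by 0.65 ± 0.08 and 0.52 ± 0.08 on the log2 scale (SE, n = 3, edgeR adjusted p = 0.00188 and 0.00433). The list median was -0.26 (camera adjusted p = 1.71e-04; adjusted p = 0.367 with an estimated correlation). Of 75 nuclear genes of oxidative phosphorylation, Ndufab1 rose (0.30) and Sdha (-0.46), Ndufa10 (-0.40) and Uqcrc2 (-0.26) fell. Adjusted over the list alone 1 fell. None of the 13 mRNAs of the mitochondrial genome passed, over all genes or adjusted over the list alone. The transcript mt-Co1, with the smallest p, had a log2 fold change of -0.32 ± 0.14 (edgeR adjusted p = 0.205, and 0.0417 with no filter). Their medians were -0.03 and -0.18 and neither list passed (camera adjusted p = 0.180 and 0.0765; adjusted p = 0.849 and 0.817 with an estimated correlation). With 1 library left out these medians ranged from -0.096 to -0.027 and from -0.31 to -0.055. Both passed with no filter, in limma-voom and without CREBH-KO 1, and the mitochondrial mRNAs also without WT 2 or WT 3 and with the GC or length correction (adjusted p of 0.00380 to 0.0478). The 4 calls in oxidative phosphorylation were each lost without WT 2, WT 3, CREBH-KO 2 or CREBH-KO 3, except that of Sdha without WT 3, those of Ndufab1 and Uqcrc2 also without CREBH-KO 1, and that of Uqcrc2 also without WT 1 (adjusted p up to 0.175).

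Core clock genes and their outputs differed between the groups. Of 17 clock genes, 11 fell and 2 rose (11 and 4 adjusted over the list alone), with a median of -0.80 (camera adjusted p = 1.04e-08; adjusted p = 0.294 with an estimated correlation). Dbp, an output gene of the clock, fell from 103.8 ± 47.1 to 5.99 ± 2.08 CPM (log2 fold change -4.11 ± 0.39 SE, n = 3, edgeR adjusted p = 4.74e-04). Bhlhe41 (-3.40 ± 0.31), Per3 (-2.67 ± 0.32) and Per2 (-1.59 ± 0.26) fell as well. Arntl, which encodes BMAL1, the positive arm of the clock, rose from 3.89 ± 2.58 to 12.9 ± 1.08 CPM (1.71 ± 0.37), with its relative Npas2 (1.24 ± 0.33). The labels give the length of the fast and not the hour at which livers were taken. The calls of Arntl (without WT 2, CREBH-KO 2 or CREBH-KO 3, and in edgeR's robust fit) and Npas2 (without any 1 library) were lost, with adjusted p up to 0.141.

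Genes of pericentral hepatocytes, which lie around the central vein of the lobule, were lower. Of 16, 11 fell and none rose (13 fell adjusted over the list alone). Glul, the glutamine synthetase of the innermost layer, fell from 1124 ± 214 to 515 ± 29.0 CPM (log2 fold change -1.13 ± 0.13 SE, n = 3, edgeR adjusted p = 0.00135). Cyp2e1 (-1.06 ± 0.11), Cyp27a1 (-0.77 ± 0.08) and the ammonium transporter Rhbg (-1.45 ± 0.31) fell with it. Their median was -0.84 (camera adjusted p = 4.08e-16; adjusted p = 0.294 with an estimated correlation). Of 16 periportal genes, from the opposite end of the lobule, 4 rose and 3 fell (6 and 3 adjusted over the list alone). The serine dehydratase-like gene Sdsl rose by 1.73 ± 0.11 and Apoa4 fell. The periportal median was 0.19 (0.099 to 0.28 with 1 library left out), and the list did not pass (camera adjusted p = 0.0671, and 0.711 with an estimated correlation). It passed under several alternatives, among them without WT 3, CREBH-KO 2 or CREBH-KO 3 (adjusted p of 0.00838, 0.0131 and 0.0321) and with scaling by library size alone (0.0417). Most exonic bases of Rhbg are shared with an overlapping gene of the same strand, so its value is uncertain, and its call was lost without WT 2, CREBH-KO 2 or CREBH-KO 3 (adjusted p up to 0.0739).

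**Figure D2:**
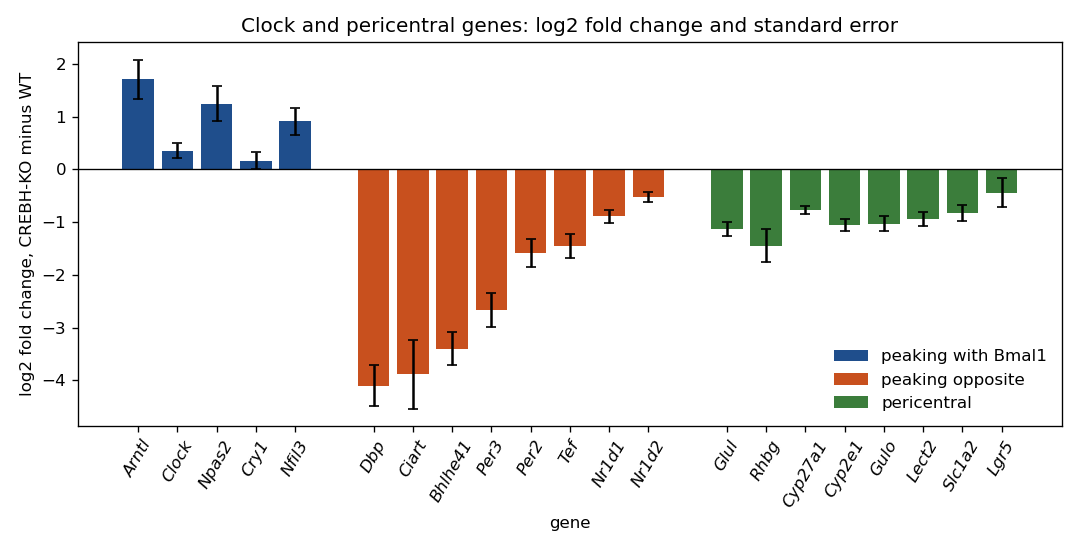
Log2 fold changes (CREBH-KO minus WT; bars, with standard errors) of 5 clock genes that peak with Bmal1 (blue), 8 that peak opposite to it (orange) and 8 pericentral genes (green). The first set has a median of 0.91 and the second of -2.13; all 8 pericentral genes shown lie below 0, and not every bar passed the test.

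Among the marker lists of other liver cell types that could be tested as sets, that of stellate cells and fibroblasts passed. Of 15 stellate cell and fibroblast markers, 4 rose and none fell (5 rose adjusted over the list alone). The matrix protein gene Dcn rose from 84.8 ± 5.59 to 125 ± 9.98 CPM (log2 fold change 0.56 ± 0.09 SE, n = 3, edgeR adjusted p = 0.00552), Rgs5 by 0.68 ± 0.11 and the actin gene Acta2 by 1.48 ± 0.33. The median was 0.56 (camera adjusted p = 5.19e-04; adjusted p = 0.367 with an estimated correlation). Of 14 Kupffer cell and macrophage markers only Cd163 changed (-2.14 ± 0.43), of 9 cholangiocyte markers only Sox9 (0.96 ± 0.23), and of 10 proliferation markers only Ube2c (-2.09 ± 0.48), each also called adjusted over the list alone. None of the 10 lymphocyte, 14 sinusoidal endothelial and 6 erythroid markers changed, over all genes or adjusted over the list alone. These 6 lists did not pass as sets (camera adjusted p of 0.602, 0.900, 0.581, 0.291, 0.272 and 0.882 in the order named). Lymphocyte markers, with a median of 0.45 (0.21 to 1.25 with 1 library left out), did pass without WT 3 (adjusted p = 0.00301), with no filter (0.0262) and against CREBH-KO 1 alone (0.0419), and cholangiocyte markers without CREBH-KO 1 (0.0354). Of the 8 adipocyte markers, 3 were expressed enough to be tested and all 3 fell (Cfd, Pparg by 0.97 ± 0.17 and Car3 by 1.37 on the log2 scale). Adipoq, Plin1, Lep, Retn and Adig were too low to be tested, so these falls do not show a change in adipocytes. Only 2 neutrophil markers and 1 pancreatic marker could be tested and none passed. The calls of Cd163 (without CREBH-KO 3), Sox9 (without WT 1, WT 2, CREBH-KO 1 or CREBH-KO 2), Acta2 (without any 1 library except CREBH-KO 2) and Ube2c (without any 1 library) were lost, with adjusted p up to 0.113.

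**Figure D3:**
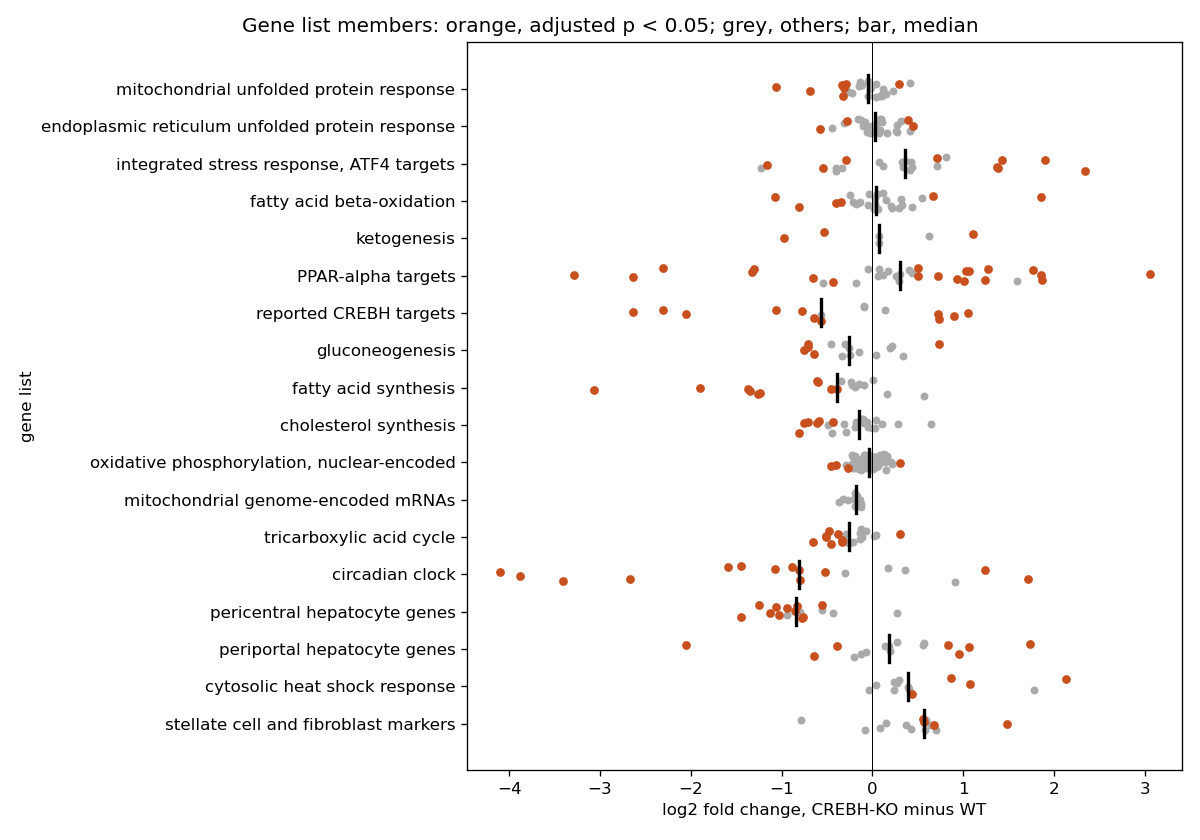
Log2 fold changes (CREBH-KO minus WT) of the members of 18 gene lists; each point is a gene, orange where the adjusted p was under 0.05 and grey elsewhere, and black bars are list medians. The medians reach from -0.84 for pericentral genes to 0.56 for stellate cell and fibroblast markers.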

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

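Corrections for GC content and length and the fits without gene families picked by symbol or without 42 to 56 Mb of chromosome 11 were chosen after seeing the data. The families (Mup, Cyp, Serpina, Gstm, Acot, Olfr) also hold genes outside the near-identical groups, such as Cyp27a1 and Serpina12. Of the 133 changed named genes, 88 kept their call in every fit that left out 1 library, as did 13 of the 17 called lists. All 133 kept their direction, but this tests little, since the groups did not overlap for 1614 of the 1616 changed genes. With a library left out, changed genes numbered 658 to 1806, higher 209 to 659, lower 449 to 1147, at least 2-fold 331 to 609 (135 to 290 higher, 196 to 390 lower). Creb3l3 kept its direction and call in every alternative. CREBH-KO 1 alone against WT gave 228 changed, 76 higher, 152 lower, 178 at least 2-fold, 65 and 113 by direction; a lone library is assumed to vary like the WT libraries. With no filter 2456 changed, 929 higher, 1527 lower, 418 at least 2-fold lower. The other thresholds gave 2483 (0.1) and 540 (0.01). DESeq2 called 2123 genes and limma-voom 1610. Camera with an estimated correlation called 0 lists, against 17 with the preset correlation. Fry called 8, of which 1 was not called by camera. The mitochondrial unfolded protein response list, with a median of -0.046, passed by fry and, at -0.069, with no filter. With scaling by library size its median was 0.029, while the set test kept its direction and did not pass. Directions turned for results that did not pass: Hspd1 (0.030) and mitochondrial protein import (0.075) with scaling by library size; beta-oxidation (0.016) and erythroid markers (-0.046) with no filter; and, with CREBH-KO 1 alone, beta-oxidation (-0.0067), oxidative phosphorylation (0.0086), urea cycle (0.059), cholangiocyte (0.34) and proliferation markers (-0.0090), where some medians kept their sign and the set test turned. PPAR-alpha targets, called in the main analysis, turned in the test without the gene families picked by symbol (median 0.12). With a library left out, ranges in which the test turned were -0.47 to 0.15 (Hbb-bt), -0.025 to 0.076 (endoplasmic reticulum list), -0.0099 to 0.067 (beta-oxidation), -0.064 to 0.23 (acute phase), -0.43 to 0.19 (Kupffer), -0.41 to 0.11 (cholangiocyte) and -0.27 to 0.16 (erythroid). Medians crossed 0 while the set test kept its direction for proliferation markers (-0.40 to 0.21), mitochondrial protein import (-0.045 to 0.0084) and the urea cycle (-0.20 to 0.00028). The cause was not tested. Depth was not varied. In data simulated at these library sizes, 29.9% of 67 genes with a mean above 1 CPM changed 1.5-fold were recovered.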

Other observations

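Male-biased liver genes were lower as a list in CREBH-KO livers. Of 19 tested male-biased genes, 9 fell and 1 rose (10 and 3 adjusted over the list alone), with a median of -0.57 (camera adjusted p = 1.15e-05; adjusted p = 0.471 with an estimated correlation). The complement regulator Susd4 fell by 1.42 ± 0.12 and the bile acid hydroxylase Cyp7b1 by 1.61 ± 0.28 on the log2 scale, whereas the protease inhibitor gene Serpina1e rose by 1.62 ± 0.15 (SE, n = 3). Of the major urinary protein (Mup) genes and pseudogenes on chromosome 4 between 59964294 and 62150863, counted after their values were seen, 24 of 31 tested fell and none rose, with a median of -2.42. These near-identical genes share reads, so the fall of any 1 copy is uncertain. Of 11 tested female-biased genes, 3 rose and none fell (3 and 1 adjusted over the list alone), led by Cyp2b9, from 0.0879 ± 0.0221 to 2.29 ± 1.31 CPM. The median of this list was -0.20 (-0.39 to -0.10 with 1 library left out) and its mean 0.44, and it did not pass (camera adjusted p = 0.374, and 0.697 with an estimated correlation). Of 21 genes of xenobiotic metabolism, 9 fell and none rose, with the same counts adjusted over the list alone, and of 15 tested genes of bile acid synthesis and transport 5 fell and none rose (6 and 1). Cyp2a5, a coumarin hydroxylase, fell from 2017 ± 207 to 432 ± 37.0 CPM, Cyp2c50 by 1.33 ± 0.17 and the bile acid uptake transporter gene Slc10a1 by 0.50 ± 0.08 on the log2 scale. The median of the second list, -0.41, was -0.18 without WT 1 and -0.25 without CREBH-KO 3. Both lists passed (camera adjusted p = 3.05e-09 and 8.46e-04, but 0.294 and 0.367 with an estimated correlation). Neither passed once all Mup, Cyp, Serpina, Gstm and Olfr genes and several Acot genes were left out (camera adjusted p = 0.225 and 0.0613). That step took out list members beyond the near-identical genes, such as Cyp1a2 and Cyp27a1. It therefore cannot tell whether the calls rest on shared reads.

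The cell cycle inhibitor gene Cdkn1a (p21) rose from 7.77 ± 0.813 to 46.9 ± 16.7 CPM, the phosphatase gene Dusp1 by 1.33 ± 0.23, Klf6 by 0.81 ± 0.13 and Gadd45b by 2.36 ± 0.31 on the log2 scale (SE, n = 3). Of 11 tested immediate early genes 4 rose and none fell (6 adjusted over the list alone; camera adjusted p = 1.71e-04; adjusted p = 0.367 with an estimated correlation). Of 13 cytosolic heat shock genes 4 rose, among them Hsp90aa1 and Hspa1a, and none fell (6 adjusted over the list alone; camera adjusted p = 5.76e-04; adjusted p = 0.630 with an estimated correlation). Of 19 autophagy genes 4 fell, among them Wipi1 (-0.74 ± 0.12) and the kinase gene Ulk1, and none rose (6 fell adjusted over the list alone; camera adjusted p = 0.0173; adjusted p = 0.294 with an estimated correlation). Of 76 cytosolic ribosomal protein genes 3 rose, with Rps28 at 0.28 and Rpl7l1 at 0.31, and none passed adjusted over the list alone. The list passed with a median of 0.14 (camera adjusted p = 2.20e-04; adjusted p = 0.698 with an estimated correlation). The heat shock median was 0.39, and 0.26 without CREBH-KO 2. The heat shock and ribosomal lists did not pass against CREBH-KO 1 alone (adjusted p = 0.588 and 0.0540). The single calls of Hsp90aa1 (without WT 2), Hspa1a (without any 1 library except CREBH-KO 1), Ulk1 (without any 1 except WT 1 and CREBH-KO 3), Rps28 (without any 1 except WT 1) and Rpl7l1 (without any 1 except CREBH-KO 1) were lost, with adjusted p up to 0.145.

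The remaining lists did not pass in the main analysis. The acute phase list held 4 genes that rose, including haptoglobin (Hp, from 3156 ± 502 to 5574 ± 234 CPM) and Itih3 (0.58 ± 0.09), and 2 that fell of 24 (6 and 4 adjusted over the list alone; median 0.10, mean -0.05; camera adjusted p = 0.419, and 0.0458 against CREBH-KO 1 alone). Of 11 glucocorticoid-induced genes 3 rose and 1 fell (6 and 3; camera adjusted p = 0.0671, although the list passed without any 1 library except WT 1, with adjusted p of 0.0162 to 0.0414). Of 11 tested NRF2 targets 2 rose and 1 fell (4 and 1; camera adjusted p = 0.213). Of 9 urea cycle genes 1 rose and 1 fell (2 and 3; camera adjusted p = 0.533). Among mitochondrial lists, 2 of 18 biogenesis and dynamics genes fell (also 2 adjusted over the list alone; camera adjusted p = 0.125, and 0.0196 with no filter), the DNA polymerase gene Polg (-0.48 ± 0.07) and the fusion gene Mfn2 (-0.54 ± 0.11). Of 77 mitochondrial ribosomal protein genes 1 rose (Mrps6) and 1 fell (Mrpl45), with the same counts adjusted over the list alone (camera adjusted p = 0.533). None of 22 import genes changed by either count (camera adjusted p = 0.825). The calls of Mfn2 (without WT 2 or CREBH-KO 3) and Mrps6 (without WT 2, WT 3, CREBH-KO 2 or CREBH-KO 3) were lost, with adjusted p up to 0.0880.

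The splits of the libraries, the values of single WT libraries, the clock phase test and the 5 Mb windows of the paragraphs that follow were chosen after the result was seen. The real split gave 1616 changed genes and the other 9 of the 10 splits at most 0, so 1 of 10 reached the real count, the smallest share that 10 splits can give. Each of the other splits mixes the genotypes, so any real difference between them widens the spread within its groups. Their counts therefore do not show how many calls chance would give. In CREBH-KO 1, the genes changed between WT and the other two CREBH-KO libraries had a median 0.803 of their log2 fold change (quartiles 0.543 and 1.01) and 1283 of 1350 the same sign, where a CREBH-KO 1 simulated without any effect gave medians of at most 0.0823 and 60.2%, and single WT libraries against the other WT libraries -0.0743 to 0.118. The loss of read files in CREBH-KO 2 and 3 as the whole cause stays open all the same, since CREBH-KO 1 is 1 library and its median passed the bound of 0.8 set beforehand by less than the SD of 0.105 between the WT values. DNA of another mouse strain carried by the knockout line stays open too: within 10 Mb of Creb3l3 the odds ratio of being changed was 1.07 (95% interval 0.685 to 1.60, two-sided Fisher's exact p = 0.751), and 30 windows of 2 Mb elsewhere held 3 or more genes of different family names changed at least 2-fold, against a median of 32 in 1000 shuffles, a gap smaller than their SD of 4.28. A candidate region is 45 to 50 Mb of chromosome 11, where 7 of 34 genes changed at least 2-fold. The exact hypergeometric test, one-sided for more changed genes, gave p = 0.0436 adjusted over 536 windows of 5 Mb, close to the threshold of 0.05. Unlike in the 2 Mb windows, genes of one family name were counted separately. The 7 genes include both Havcr1 and Havcr2, the latter at 0.0425 CPM in WT and 0.365 CPM in CREBH-KO. Btnl9 also lies inside the region, with Pttg1 and Lyrm7 nearby. The Mup cluster on chromosome 4 was the other window past the threshold (25 of 54).

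The clock genes showed a pattern that a difference in phase could give. The 5 genes that peak with Bmal1 had a median log2 fold change of 0.91 (all above 0, with Arntl and Npas2 past the test) and the 8 that peak opposite to it a median of -2.13 (all below 0), a difference of 3.04. This is consistent with livers taken at different phases of the clock. An effect of the genotype on the clock would give the same values, and since the hour of collection is not in the labels, it stays open as well; either may also move clock-driven metabolic genes among the other lists.

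The lower pericentral genes may reflect fewer pericentral hepatocytes in the pieces sampled, but the comparison made cannot decide this. The 7 genes most restricted to that layer had a median log2 fold change of -0.83 ± 0.13 (SE over genes), against -0.84 for the whole list. Without Rhbg, left out after its overlap with another gene was seen, their median was -0.81 ± 0.10 over 6 genes. The sign of such a loss set beforehand was a fall at least as large as the list's, which was missed by less than the SE. These genes belong to the list, so the medians are not independent. The SE also treats genes that can vary together as separate. The lost read files as the cause stay open: the list's median was -0.79 in CREBH-KO 1 and -0.92 in CREBH-KO 2 and 3, against the same WT libraries, while single WT libraries against the other WT libraries gave -0.39 to 0.44. Lower expression within the same cells, through the genotype, was not tested and stays open.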
